A study of Gallus gallus with 6 samples.

How the data were processed

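Gene expression was measured by bulk RNA sequencing in the bursa of Fabricius of chicken embryos on embryonic day 18. The bursa is the organ in which birds form and diversify their B cells. The labels give 6 samples, 3 wild-type and 3 RAG1 knockout, and the series' design text calls the replicates biological. Whether each sample came from a single embryo is not given in the sources used here. If some were split from shared material, the p values measure only the spread between these samples.

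The authors deposited a single table of raw counts per gene, with a column per sample. Per the submitters' processing notes, STAR 2.7.9a and HTSeq were named as tools and GRCg7b as the genome build. The version of HTSeq, its strand setting and its treatment of reads that match several genes are not given in the sources used here. Overlapping genes, antisense genes and near-identical copies are therefore reported as uncertain. Per the labels, RNA was extracted with Trizol and libraries were made with a stranded total RNA kit, while the molecule field names polyA RNA. How transcripts without a poly(A) tail were retained is thus open, which bears on histone genes.

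The table held 25466 rows. Of these, 10 carried a date in place of a gene name, as spreadsheet programs write for some symbols, and were left out of library sizes and tests. They held 0.0669% to 0.0711% of each library's counts. Of the 25456 rows that name a gene, 25219 were matched to a RefSeq gene table of GRCg7b, the build named in the notes, 13 of them by locus tag. Coordinates are from that table and are counted from 1. No genome sequence was used. Members of gene lists were matched on the exact symbol. BLNK had no row under that symbol and has no value here.

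The columns of RAG1 knockout replicates 1 and 2 were identical in all 25466 rows. Every other pair of columns differed in at least 19463 rows. The identical columns were counted as 1 library, because they differ by less than sampling noise, so 5 distinct libraries entered the tests, 3 wild-type and 2 knockout-labelled. The design set before the data were examined had assumed 6 libraries, and a fit that keeps both copies is given with the alternatives. Which replicate number the shared column belongs to is unknown, and it is called replicate 1 here.

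Total counts per library were 29464591 to 36430797. At this depth, counting error is small for most genes, and replicate spread sets the precision. The biological coefficient of variation was 0.278. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only, as does the limit of 3 counts used for a group at 0.

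Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with genotype as the group, library sizes were scaled by TMM, and the quasi-likelihood test compared knockout-labelled with wild-type libraries, two-sided and without covariates. P values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Log2 fold changes are knockout-labelled minus wild-type, and standard errors (SE) come from the fitted coefficient and its F statistic. Levels are TMM-normalised CPM (counts scaled to a common library size), given as mean ± SD over libraries.

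The 24 gene lists, the rule for named genes and the alternatives, unless stated otherwise, were all fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes and adjustment over the 24 lists. Camera with an estimated correlation and fry were run beside it. A list's calls are given over all genes tested and, where so stated, adjusted over the list alone. The named genes were a fixed set of 20 (among them RAG1, RAG2, DNTT and B cell and tissue markers), the 8 higher and 8 lower genes with the largest change, up to 3 members of each list with the lowest p, and the 5 genes with the most counts. Some genes that this rule takes are not reported here. The genes with the largest change had to be called, carry a symbol that is not a LOC or Ensembl number, reach a mean of 1 CPM in the higher group and have no overlap between genotypes. A list without a called member is represented by the 2 members with the lowest p.

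The procedure was tested on simulated counts for 2 against 3 libraries and 16141 genes. Of 50 genes each, it recovered 32% of those raised 2-fold, 86% of those raised 4-fold, 16% of those lowered to 0.5 and 74% of those lowered to 0.25 of their level. It made 121 calls, of which 14 were false. Camera called a simulated list that moved and did not call a list left still. Simulated genes varied independently of each other, so this does not test list p values where genes are correlated.

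Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom with and without quality weights, robust dispersions, other thresholds, the replicate number as a block, leaving out each library, leaving out Z and W genes, and leaving out the 10 genes with the most counts. Further alternatives were chosen after seeing the data. These counted the identical columns as 2 libraries, added the share of W-linked counts as a covariate, or left out both doubted libraries. The doubted libraries are wild-type replicate 1, for its W-linked share, and the identical knockout-labelled columns. Alternatives that need gene GC content were not run, since no genome sequence was used. Plots were drawn with matplotlib.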

Results

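The counts describe the bursa of Fabricius at embryonic day 18 in wild-type chickens and in chickens labelled RAG1 knockout. RAG1 is a subunit of the recombinase that joins V, D and J segments into functional antigen receptor genes. Total counts were 32164262, 29464591 and 31834563 in wild-type replicates 1, 2 and 3. They were 36430797 in the identical columns of knockout-labelled replicates 1 and 2, counted as 1 library, and 32686616 in replicate 3. Over 16512 tested genes, the first principal component held 46.7% of the variance. The knockout-labelled libraries lay at 52.9 and 59 on it, and wild-type replicates 1, 2 and 3 at -8.5, -44.1 and -59.1.

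Libraries also differed in reads from the W chromosome, which female birds (ZW) carry and male birds (ZZ) lack. The labels give no sex. W-linked genes took 0.0412% of counts in wild-type replicate 1 (95% interval 0.0405 to 0.0419), 0.146% in replicate 2 (0.145 to 0.148) and 0.141% in replicate 3 (0.14 to 0.142). The share was 0.00344% in knockout-labelled replicate 1 (0.00326 to 0.00364) and 0.167% in replicate 3 (0.166 to 0.169). Z-linked genes took 4.99% of counts in wild-type replicate 1 and 5.24% in knockout-labelled replicate 1, against 3.63% to 3.9% in the other libraries. Mitochondrial genes took 0.143% to 0.66% in wild-type and 0.318% and 0.384% in knockout-labelled libraries.

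RAG1 transcripts were present in every library and were not lower in those labelled knockout. RAG1 (gene 423164, GRCg7b chromosome 5, 19040483 to 19050348) stood at 7.08 ± 3.31 CPM in wild-type (n = 3) and 10.9 ± 0.805 CPM in knockout-labelled libraries (n = 2). The log2 fold change was 0.62 (SE 0.40, adjusted p = 0.354), within the spread between replicates. Where in the gene the knockout lies is not given in the sources used here, so reads from outside it check nothing. RAG1 counts therefore do not check the genotype, which is taken from the labels. RAG1 also overlaps TRAF6 in the annotation, which makes its counts uncertain. RAG2, the partner subunit, had 26.7 ± 2.21 CPM in wild-type and 12.7 ± 6.19 CPM in knockout-labelled libraries (log2 fold change -1.07, SE 0.31, adjusted p = 0.0895). Its annotated span of 565.7 kb contains C11orf74, so its counts are uncertain too. DNTT, which adds nucleotides at recombined joints, had 4.36 ± 1.07 and 2.49 ± 0.19 CPM (adjusted p = 0.187).

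The comparison of genotypes asks how bursal gene expression, and B cell development with it, differs where RAG1 is labelled as knocked out. Among called genes with a symbol, the largest differences lay in immunoglobulin genes. IGLL1, annotated as an immunoglobulin lambda-like gene (gene 416928, chromosome 15, 7933262 to 7955461), fell from 285 ± 10.8 CPM in the 3 wild-type libraries to 1.54 ± 0.325 CPM in the 2 knockout-labelled libraries. That is a 184-fold difference, with a log2 fold change of -7.52 (SE 0.23, adjusted p = 8.71e-05). VH26L1, annotated as an antigen receptor constant region (gene 431524, chromosome 35, 111993 to 156486), fell from 181 ± 4.53 to 1.08 ± 0.746 CPM, by 166-fold (log2 fold change -7.37, SE 0.44, adjusted p = 0.00467). These were the only 2 genes with an adjusted p under 0.01 in edgeR's quasi-likelihood test with all 5 libraries. IGLL1 stayed past the threshold of 0.05 whichever single library was left out, and VH26L1 did so except without wild-type replicate 2 (adjusted p = 0.0621).

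In all, 788 of the 16512 genes changed, 317 higher and 471 lower in knockout-labelled libraries, and 186 and 313 of these by at least 2-fold. Higher genes made up 40.2% of the calls, and 52.1% with upper-quartile factors and 55.5% with library totals. Most calls lay close to the threshold, and their number rested on single libraries. It was 2284 without wild-type replicate 1, 1 without wild-type replicate 2 and 1078 without wild-type replicate 3. It was 103 without knockout-labelled replicate 1 and 2 without knockout-labelled replicate 3. In each of these 5 fits all 788 genes kept their direction and an unadjusted p under 0.05. That they did so was close to given and is no independent evidence, because the 788 genes were chosen in a fit on the same libraries. Levels for named genes from each library are plotted on a log axis.

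**Figure D1:**
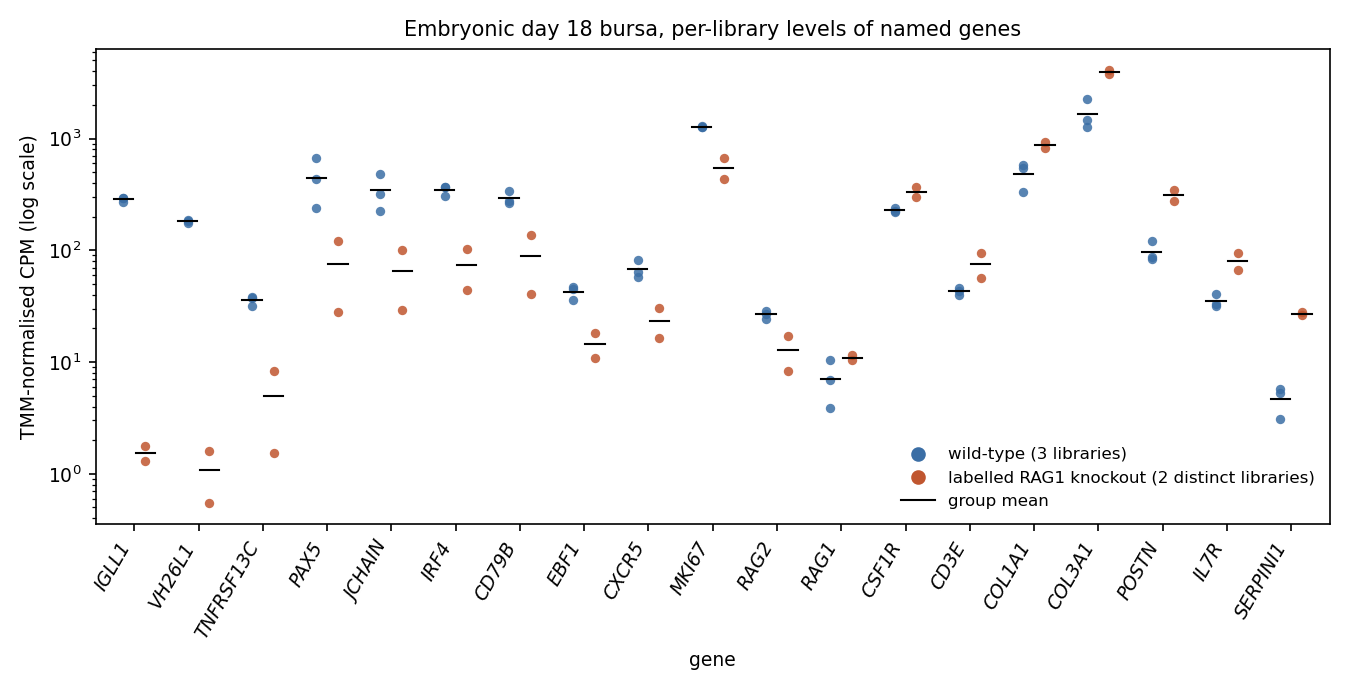
Normalised CPM on a log scale for 19 named genes, with a point per library (blue wild-type, orange labelled RAG1 knockout) and a bar at each group mean. IGLL1 lies at 272.3 to 291.2 CPM in wild-type and at 1.31 and 1.77 CPM in knockout-labelled libraries, whereas RAG1 overlaps between groups.

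Genes of B cell identity and antigen receptor signalling fell as a group. Of 31 tested members, 16 fell and 15 did not pass, and 29 had a negative log2 fold change; 22 fell when adjusted over the list alone. The list's median log2 fold change was -1.31 (camera adjusted p = 2.34e-12; adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.0334). Besides IGLL1, SWAP70, which acts in B cell activation, fell from 569 ± 51.7 to 173 ± 41.1 CPM (log2 fold change -1.72, SE 0.20, adjusted p = 0.0326). INPP5D, an inositol phosphatase that limits receptor signalling, fell from 181 ± 5.26 to 69.02 ± 14.9 CPM (-1.39, SE 0.18, adjusted p = 0.0338). EBF1, a transcription factor of B lineage commitment, fell from 42.5 ± 6 to 14.6 ± 5.13 CPM (-1.54, SE 0.27, adjusted p = 0.0363). Without wild-type replicate 2 or knockout-labelled replicate 3 a single member, IGLL1, remained called, and 10 members passed without knockout-labelled replicate 1.

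Other B cell genes did not pass, and the knockout-labelled libraries differed from each other in them. PAX5, the B lineage identity factor, which lies on the Z chromosome, had 445 ± 212 CPM in wild-type and 74.7 ± 65.9 CPM in knockout-labelled libraries (log2 fold change -2.57, SE 0.68, adjusted p = 0.0718). TNFRSF13C, the BAFF receptor, had 35.7 ± 3.35 and 4.95 ± 4.82 CPM (-2.85, SE 0.63, adjusted p = 0.0516). CD79B, the signalling chain of the B cell receptor, had 292 ± 39.4 and 88.7 ± 68.3 CPM (-1.72, SE 0.47, adjusted p = 0.077). In knockout-labelled replicate 3 alone CD79B stood at 40.4 CPM, against 137 CPM in replicate 1. CXCR4, a homing receptor, had 499 ± 155 and 196 ± 91.5 CPM (adjusted p = 0.0737). These B cell transcripts remained measurable in both knockout-labelled libraries.

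Chosen after their values were seen, counts on annotated V segments were summed by chromosome. On chromosome 35, where VH26L1 lies, the 24 segments with a row held 225, 110 and 162 counts in wild-type replicates 1, 2 and 3, against 3 counts in the knockout-labelled libraries together. The ratio of normalised totals was 130, with a 95% counting interval of 44.4 to 635. The single V segment on chromosome 15, which lies within the span of IGLL1, held 138 counts in wild-type and 0 in knockout-labelled libraries, at least 36.2-fold lower at a floor of 3 counts over the group, while the two-sided 95% counting interval begins at 29.1. V segments on chromosome 27 held 351 and 60 counts (log2 fold change -2.18, SE 0.46). With p values adjusted over the 5 chromosomes, the differences on chromosomes 35, 15 and 27 passed (adjusted p = 0.000282, 0.00148 and 0.0034). Those on chromosome 2, with 239 and 197 counts, and chromosome 1, with 9 and 18 counts, did not (adjusted p = 0.901 and 0.307). Which antigen receptor the segments on chromosomes 27, 2 and 1 belong to was not determined. V segments of one array resemble each other, so counts of single segments are uncertain.

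**Figure D2:**
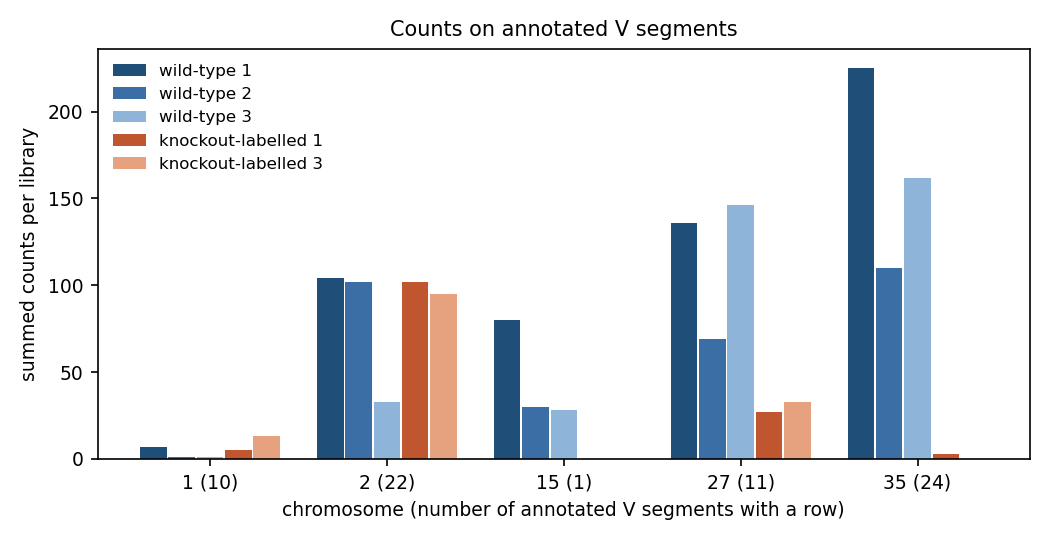
Summed raw counts per library (bars, from 0) on annotated V segments, by chromosome, with the number of segments in brackets; blue shades are wild-type and orange shades labelled RAG1 knockout. Bars on chromosome 35 reach 110 to 225 counts in wild-type and 3 and 0 counts in knockout-labelled libraries, while those on chromosome 2 overlap.

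Chicken B cells diversify their immunoglobulin genes mainly by gene conversion, which uses homologous recombination. Of 32 genes of gene conversion and homologous recombination, 9 fell and 23 did not pass (18 lower when adjusted over the list alone). The list's median was -0.69 (camera adjusted p = 1.3e-07; adjusted p = 0.553 with an estimated correlation). BRCA2, which acts in homologous recombination, fell from 994 ± 384 to 242 ± 54.8 CPM (-2.04, SE 0.35, adjusted p = 0.0363). BARD1, the partner of BRCA1, fell by 1.17 on the log2 scale (SE 0.19, adjusted p = 0.0338) and the helicase gene RAD54B by 1.37 (SE 0.24, adjusted p = 0.0362). No member passed without wild-type replicate 2 or knockout-labelled replicate 3, 2 passed without knockout-labelled replicate 1 and 15 without wild-type replicate 1.

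Among 15 genes of V(D)J recombination and end joining, POLL, a repair polymerase, fell from 181 ± 14.1 to 78.7 ± 23.7 CPM (log2 fold change -1.20, SE 0.21, adjusted p = 0.0368), and 14 did not pass. The list had a median of -0.27 (camera adjusted p = 0.00627; adjusted p = 0.571 with an estimated correlation), and 6 were lower when adjusted over the list alone. Of 13 genes of plasma cells and immunoglobulin secretion, IRF4, a factor of B cell activation and plasma cell fate, fell from 346 ± 33.3 to 73.4 ± 42 CPM (-2.24, SE 0.36, adjusted p = 0.0338). JCHAIN, which joins polymeric immunoglobulin, had 344 ± 132 and 65.04 ± 50.4 CPM (adjusted p = 0.0572). This list did not pass (median -0.06, camera adjusted p = 0.647), and 1 member was higher and 3 lower when adjusted over the list alone. The calls of POLL and IRF4 were lost without wild-type replicate 2 or knockout-labelled replicate 3, and that of POLL also without knockout-labelled replicate 1. Without wild-type replicate 1, 2 recombination genes fell, and 2 plasma cell genes rose and 3 fell. Without knockout-labelled replicate 1, the recombination median was -0.68 and 3 plasma cell genes fell.

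All 32 tested genes of the cell cycle and DNA replication list had a negative log2 fold change, 9 fell, and 28 were lower when adjusted over the list alone. The median was -0.88 (camera adjusted p = 2.34e-12; adjusted p = 0.571 with an estimated correlation). MKI67, a marker of cycling cells, fell from 1278 ± 23.4 to 550 ± 165 CPM (-1.22, SE 0.22, adjusted p = 0.0371). KIF11, a mitotic motor, fell by 1.08 on the log2 scale (SE 0.17, adjusted p = 0.0338), and MCM4, part of the replicative helicase, by 0.87 (SE 0.16, adjusted p = 0.039). Of 39 histone genes, H2AFX fell (-1.48, SE 0.27, adjusted p = 0.039), the linker histone gene HIST1H101 rose (0.81, SE 0.14, adjusted p = 0.0368) and 37 did not pass. The histone list had a median of -0.70 (camera adjusted p = 0.000279; adjusted p = 0.629 with an estimated correlation) and, as a family of near copies, uncertain single counts. No member of either list passed without wild-type replicate 2, knockout-labelled replicate 1 or knockout-labelled replicate 3. Without wild-type replicate 1, 27 cell cycle and 19 histone genes were lower and 1 histone gene was higher, and the histone median was -0.47 without knockout-labelled replicate 3.

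In the same libraries, all 34 genes of mesenchyme and extracellular matrix had a positive log2 fold change, 7 rose, and 22 were higher when adjusted over the list alone. The median was 0.85 (camera adjusted p = 1.43e-10; adjusted p = 0.571 with an estimated correlation). POSTN, a matrix protein, rose from 97.2 ± 20.6 to 311 ± 51.7 CPM (1.68, SE 0.21, adjusted p = 0.0326). The mesenchymal transcription factor gene PRRX1 rose by 1.37 (SE 0.22, adjusted p = 0.0338) and the collagen gene COL14A1 by 0.96 (SE 0.15, adjusted p = 0.0338). COL1A1 had 482 ± 134 and 882 ± 77.5 CPM (adjusted p = 0.0866). Of 23 endothelial genes 3 rose, among them the lymphatic markers PDPN (1.17, SE 0.18, adjusted p = 0.0338) and LYVE1 (1.35, SE 0.23, adjusted p = 0.0362), with a median of 0.93 (camera adjusted p = 7.66e-07; adjusted p = 0.572 with an estimated correlation). The mean log2 CPM of the mesenchyme list was 6.55, 5.85 and 6.06 in wild-type replicates 1, 2 and 3. It was 6.98 and 7.15 in knockout-labelled replicates 1 and 3. For the endothelial list these values were 3.52, 2.73 and 2.59 in wild-type, against 3.87 and 3.96. In both lists wild-type replicate 1 lay nearest to the knockout-labelled libraries. These lists had 25 and 17 higher members without wild-type replicate 1, and 4 each without wild-type replicate 3. Without wild-type replicate 2 or knockout-labelled replicate 3 no member of either list passed, and without knockout-labelled replicate 1 a single mesenchyme gene did.

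Of 34 epithelial genes tested, 5 rose and 29 did not pass, and 10 were higher when adjusted over the list alone. The median was 0.49 (camera adjusted p = 1.65e-05; adjusted p = 0.553 with an estimated correlation). ELF3, an epithelial transcription factor, rose from 202 ± 15.9 to 389 ± 16.2 CPM (0.94, SE 0.14, adjusted p = 0.0338). OCLN, a tight junction protein, rose by 0.84 (SE 0.14, adjusted p = 0.0362) and the integrin gene ITGB6 by 0.77 (SE 0.14, adjusted p = 0.0378). EPCAM, a general epithelial marker, had 326 ± 52.5 and 389 ± 16.7 CPM (adjusted p = 0.387). Of 20 muscle genes ACTA2, smooth muscle actin, rose (1.30, SE 0.28, adjusted p = 0.0479), with a list median of 0.84 (camera adjusted p = 0.00011; adjusted p = 0.629 with an estimated correlation). Of 16 genes of nerve and glia 2 rose, RET (1.28, SE 0.20, adjusted p = 0.0338) and STMN2 (1.46, SE 0.24, adjusted p = 0.0338), with a median of 0.81 (camera adjusted p = 0.00895; adjusted p = 0.572 with an estimated correlation). The nerve and glia list did not pass with limma-voom and quality weights (median 0.52, adjusted p = 0.105). The mean log2 CPM of the muscle list was 5.29, 4.4 and 5.55 in wild-type replicates 1, 2 and 3, so wild-type libraries themselves spread widely. It was 5.72 and 6.3 in knockout-labelled replicates 1 and 3. When adjusted over the list alone, 10 muscle genes were higher, and 3 nerve and glia genes were higher and 1 lower. The calls in these lists were lost without wild-type replicate 2, knockout-labelled replicate 1 or knockout-labelled replicate 3, and that of ACTA2 also without wild-type replicate 3. Without wild-type replicate 1, 12 epithelial, 6 muscle and 4 nerve and glia genes were higher and 1 nerve and glia gene was lower. The nerve and glia median was 0.42 (adjusted p = 0.0426) without wild-type replicate 3, and the epithelial one 0.32 without knockout-labelled replicate 3.

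**Figure D3:**
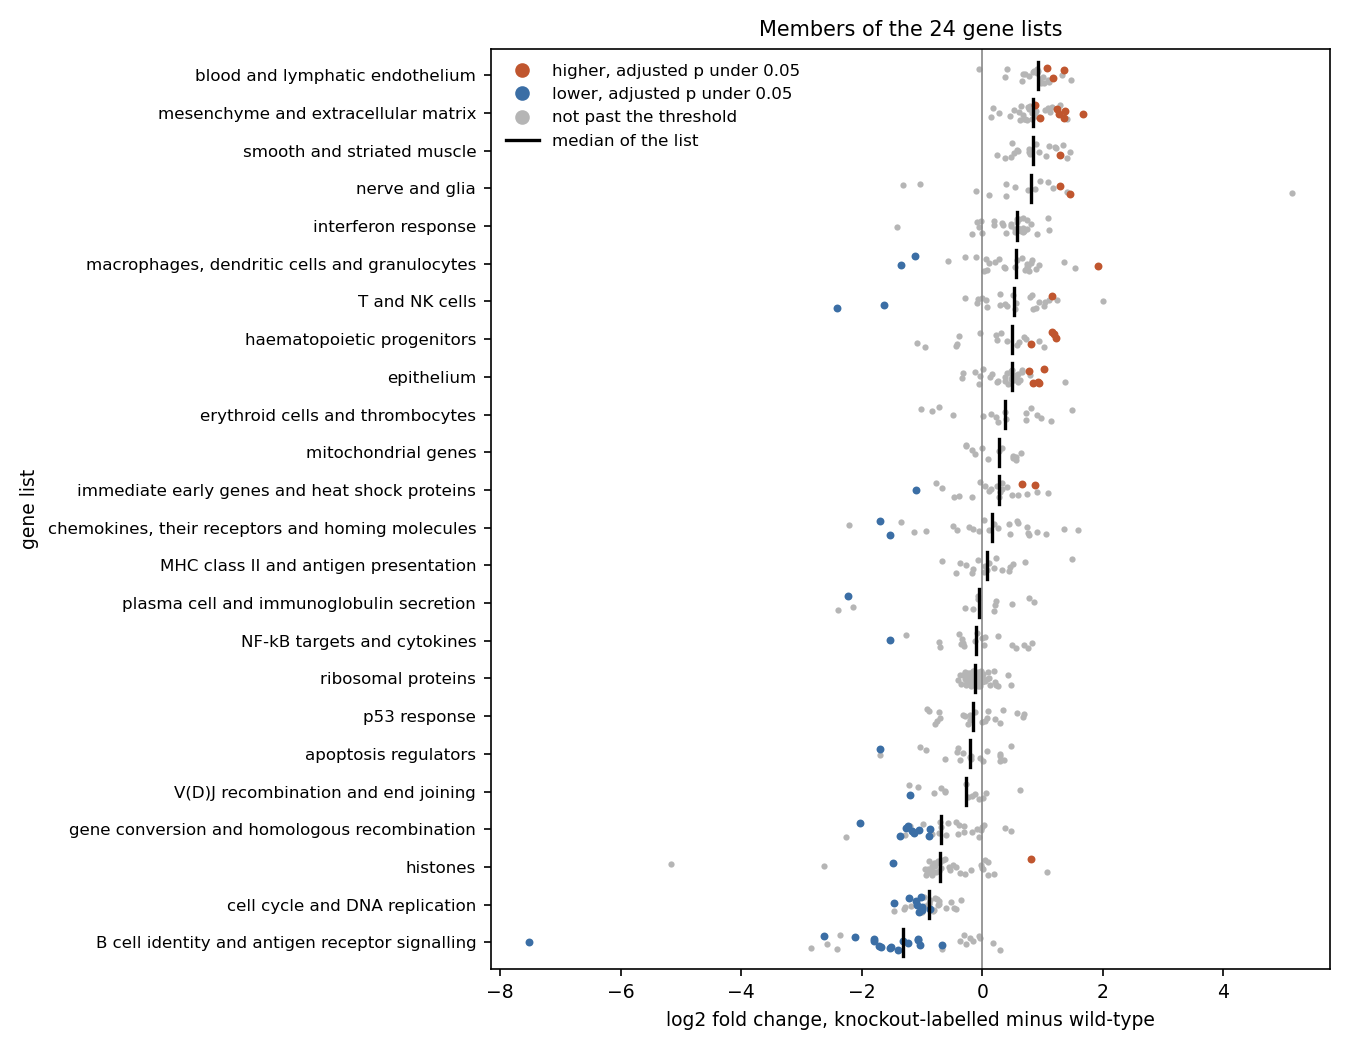
Log2 fold change of each tested member (points, knockout-labelled minus wild-type) of the 24 gene lists, with coloured points for members with an adjusted p under 0.05 and a black bar at each median. Medians run from -1.31 for the B cell list to 0.93 for endothelium.

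Lists were also examined in fits chosen after seeing the data. The fit without both wild-type replicate 1 and knockout-labelled replicate 1 leaves a single knockout-labelled library, so list medians are given for it in place of counts. They were -1.635 for B cells, -0.88 for gene conversion, -1.318 for the cell cycle and -0.417 for V(D)J recombination. For T and NK cells the median was 0.639, for macrophages 0.601, for progenitors 0.573 and for p53 response genes -0.066. With the W-linked share as a covariate, 13 B cell genes, 1 gene conversion gene and 1 mesenchyme gene passed, against 16, 9 and 7 without it. With that covariate edgeR called 0 cell cycle genes (28 had an unadjusted p under 0.05), 0 epithelial genes (13), 0 endothelial genes (8) and 0 progenitor genes (9). The list medians then stood at -1.52 for B cells, -1.06 for the cell cycle and 0.83 for mesenchyme.

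Of 20 haematopoietic progenitor genes 4 rose and 16 did not pass. The list's median was 0.50 (camera adjusted p = 0.0345; adjusted p = 0.51 with an estimated correlation), and 6 were higher and 2 lower when adjusted over the list alone. CEBPA, a myeloid transcription factor, rose from 39.6 ± 0.548 to 69.4 ± 0.474 CPM (0.81, SE 0.13, adjusted p = 0.0352). The IL-7 receptor gene IL7R, on the Z chromosome, rose by 1.20 (SE 0.20, adjusted p = 0.0352), and the stem cell factor receptor gene KIT by 1.15 (SE 0.22, adjusted p = 0.039). The list's call ended without wild-type replicate 1 (adjusted p = 0.0532), without wild-type replicate 3 (adjusted p = 0.0645), without knockout-labelled replicate 1 (adjusted p = 0.0506) and without Z and W genes (adjusted p = 0.074). It also ended with limma-voom and quality weights (adjusted p = 0.0534) and, chosen after seeing the data, without both wild-type replicate 1 and knockout-labelled replicate 1 (adjusted p = 0.0727). The calls of single members were lost without wild-type replicate 2 or either knockout-labelled library, and 6 members were higher and 1 lower without wild-type replicate 1.

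Of 26 genes of T and NK cells, ICOS, a T cell co-stimulator, rose (1.16, SE 0.20, adjusted p = 0.0362). THEMIS, a T cell signalling gene, fell (-2.41, SE 0.47, adjusted p = 0.0398), as did CD5 (-1.64, SE 0.35, adjusted p = 0.0477), which B cells can also carry. CD3E, part of the T cell receptor complex, had 43.05 ± 2.88 and 76.05 ± 27.3 CPM (adjusted p = 0.0778). The list's median was 0.53 (camera adjusted p = 0.0193; adjusted p = 0.51 with an estimated correlation), and 3 were higher and 2 lower when adjusted over the list alone; the list did not pass without knockout-labelled replicate 3 (adjusted p = 0.0698) or with limma-voom and quality weights (adjusted p = 0.0518). Of 28 genes of macrophages, dendritic cells and granulocytes, the metalloproteinase gene MMP9 rose (1.92, SE 0.35, adjusted p = 0.0378). TLR7 (-1.35, SE 0.25, adjusted p = 0.039) and the oxidase gene CYBB (-1.11, SE 0.23, adjusted p = 0.0451), both of which B cells also express, fell. CSF1R, the macrophage growth factor receptor, had 228 ± 11.1 and 332.5 ± 45.5 CPM (adjusted p = 0.0811). The median was 0.56 (camera adjusted p = 0.00202; adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.0334), and 10 were higher and 2 lower when adjusted over the list alone. The calls of these single genes were lost without wild-type replicate 2 or either knockout-labelled library, and that of CD5 also without wild-type replicate 3. Without wild-type replicate 1, 7 macrophage, dendritic cell and granulocyte genes were higher and 3 lower, and 2 T and NK cell genes were higher and 2 lower.

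Interferon response genes had a median of 0.57 (camera adjusted p = 0.00316; adjusted p = 0.656 with an estimated correlation). Of 31 tested members 25 had a positive log2 fold change and 0 passed in edgeR with all 5 libraries, while 12 had an unadjusted p under 0.05 and DESeq2 called 4. LY6E had 228 ± 58.1 and 429 ± 114 CPM (adjusted p = 0.0833), SOCS1, which lay lower, 44.8 ± 12 and 16.9 ± 9.32 CPM (adjusted p = 0.0807) and MX1 62.9 ± 39.6 and 97.8 ± 33.8 CPM (adjusted p = 0.501). The mean log2 CPM of the list was 5.32, 5.58 and 4.59 in wild-type replicates 1, 2 and 3, against 5.51 and 5.86 in knockout-labelled replicates 1 and 3. Its median was 0.30 without wild-type replicate 3 (adjusted p = 0.0426) and 0.31 with limma-voom and quality weights, and the list did not pass without knockout-labelled replicate 3 (median 0.29, adjusted p = 0.072). Erythroid and thrombocyte genes did not pass as a list (median 0.38, camera adjusted p = 0.243), but did without wild-type replicate 2 (median 0.79, adjusted p = 0.000162). Their median was 0.02 without knockout-labelled replicate 1, 0.12 without wild-type replicate 3 and 0.23 without wild-type replicate 1. In the fit without wild-type replicate 1, 1 interferon response gene was higher and 1 lower, and 1 erythroid and thrombocyte gene was lower. With all 5 libraries, no single member of the 17 was called by edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 2. HBBA, a globin gene, had 477 CPM in wild-type replicate 2, against 159 and 184 CPM in replicates 1 and 3 and 507 and 514 CPM in the knockout-labelled libraries. The globin gene HBA1 (1.14, SE 0.43, adjusted p = 0.148) and TFRC, the transferrin receptor (-1.02, SE 0.36, adjusted p = 0.132), had the lowest p in that list.

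Other lists did not pass. Genes of MHC class II and antigen presentation had a median of 0.08 (19 tested, camera adjusted p = 0.589); edgeR called 0, 4 had an unadjusted p under 0.05 and DESeq2 called 1. BLB2, an MHC class II beta chain, had 242 ± 26.8 and 397 ± 75.4 CPM (adjusted p = 0.0651) and B2M 161 ± 14.5 and 118 ± 4.69 CPM (adjusted p = 0.116). The p53 response list had a median of -0.16 (22 tested, camera adjusted p = 0.412), with 0 called by edgeR, 8 with an unadjusted p under 0.05 and 4 called by DESeq2; its lowest p values were those of PLK2, on the Z chromosome (0.70, SE 0.17, adjusted p = 0.0584), and DDB2 (-0.71, SE 0.18, adjusted p = 0.0645). Among 20 apoptosis regulators (median -0.20, camera adjusted p = 0.0936), 1 member fell and 19 did not pass, and 4 were lower when adjusted over the list alone. That call was lost without wild-type replicate 2 or knockout-labelled replicate 3, and the list had 4 lower members without wild-type replicate 1 and 2 without knockout-labelled replicate 1. That fit without wild-type replicate 1 also had 2 higher genes of MHC class II and antigen presentation, and 1 higher and 3 lower p53 response genes. The apoptosis median was -0.34 without both wild-type replicate 1 and knockout-labelled replicate 1, which leaves a single knockout-labelled library.

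Among 26 chemokines, receptors and homing molecules, 2 members fell, among them CXCR5, a follicle homing receptor of B cells (-1.53, SE 0.29, adjusted p = 0.0393). The median of that list was 0.16, its mean -0.01, camera gave an adjusted p of 0.993 with an upward sign and fry a downward one, so it showed no common direction. Of 20 NF-kB targets and cytokines (median -0.11, camera adjusted p = 0.593) IL16 fell (-1.52, SE 0.18, adjusted p = 0.0326). Of 23 immediate early and heat shock genes (median 0.27, camera adjusted p = 0.209), HSPH1 fell (-1.10, SE 0.19, adjusted p = 0.0363) while JUN (0.65, SE 0.13, adjusted p = 0.0444) and HSPA2 (0.87, SE 0.18, adjusted p = 0.0458) rose. Adjusted over the list alone, 3 chemokine-list genes were higher and 6 lower, 2 NF-kB genes were lower, and 2 immediate early and heat shock genes were higher and 2 lower. These calls were lost without wild-type replicate 2 or knockout-labelled replicate 3. All but that of CXCR5 were also lost without knockout-labelled replicate 1, and that of HSPA2 without wild-type replicate 3. Without wild-type replicate 1, 4 chemokine-list genes were higher and 5 lower, 2 NF-kB genes were higher and 3 lower, and 4 immediate early and heat shock genes were higher and 1 lower.

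As signs of RNA and library quality, 65 ribosomal protein genes had a median of -0.12 (camera adjusted p = 0.23); edgeR and DESeq2 called 0 and 1 had an unadjusted p under 0.05. RPS27 (0.43, SE 0.16, adjusted p = 0.148) and RPL34 (-0.38, SE 0.22, adjusted p = 0.323) had the lowest p values. The 13 mitochondrial genes had a median of 0.28 (camera adjusted p = 0.191), with 0 under an unadjusted p of 0.05 in edgeR and 0 called by DESeq2. ATP6 (0.55, adjusted p = 0.249) and ND6 (0.51, adjusted p = 0.292) had the lowest p values. Without wild-type replicate 1 both lists passed, at medians of -0.23 (adjusted p = 0.00329) and 0.96 (adjusted p = 9.29e-05), as they did with knockout-labelled replicate 1 left out too (adjusted p = 0.0118 and 5.35e-05), and the mitochondrial list with limma-voom and quality weights (adjusted p = 0.0133). There were 4 higher mitochondrial genes without wild-type replicate 1. The mitochondrial median was 0.10 without wild-type replicate 2 and 0.02 without knockout-labelled replicate 3. The ribosomal median changed sign without wild-type replicate 3 (0.07), as did the mitochondrial one (-0.06).

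After the immunoglobulin genes, the largest decreases among called genes with a symbol were in PLA2G10L, a phospholipase-like gene (7.35 ± 4.63 to 0.305 ± 0.0611 CPM, log2 fold change -4.57, SE 0.68, adjusted p = 0.0338), CLEC5A on the Z chromosome (-3.27, SE 0.50) and IRAG2 (75.1 ± 11.2 to 7.8 ± 2.01 CPM, -3.27, SE 0.24, adjusted p = 0.0108). RLTPR (-3.05), TBXT (-3.04) and LRRTM3 (-3.01) followed. The largest increases were in VIT, a matrix protein gene (0.885 ± 0.272 to 6.51 ± 2.2 CPM, 2.88, SE 0.40, adjusted p = 0.0338), SERPINI1, a neuronal serine protease inhibitor (4.71 ± 1.44 to 27.05 ± 1.28 CPM, 2.52, SE 0.29, adjusted p = 0.0326), and NRN1L (2.38, SE 0.44). GFRA4 (2.05), the extracellular superoxide dismutase gene SOD3 (1.99), KCNS2 (1.92), MINAR1 (1.92) and MMP9 (1.92) followed. None of these genes was called without wild-type replicate 2 or knockout-labelled replicate 3, and only IRAG2 and RLTPR were without knockout-labelled replicate 1. KCNS2 was also lost without wild-type replicate 3.

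The genes with the most counts were EEF1A1, CATHB1, SPINK5, LOC776816 and COL3A1. CATHB1, a cathelicidin antimicrobial peptide, had 8303 ± 1130 CPM in wild-type and 14090 ± 1640 CPM in knockout-labelled libraries (log2 fold change 0.76, SE 0.21, adjusted p = 0.0761). SPINK5, a protease inhibitor, had 3908 ± 862 and 8006 ± 1460 CPM (1.03, SE 0.25, adjusted p = 0.0588). COL3A1, a fibrillar collagen, rose from 1667 ± 529 to 3941 ± 185 CPM (1.24, SE 0.26, adjusted p = 0.0467), a call that held without wild-type replicate 1 and was lost without any other library. EEF1A1 (-0.15, adjusted p = 0.712) and LOC776816 (-0.06, adjusted p = 0.869) differed by less than the spread between replicates; the sign of EEF1A1 turned without wild-type replicate 3, and that of LOC776816 without wild-type replicate 3, under library totals and upper-quartile factors, and with quality weights.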

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

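Alternatives named as added were chosen after seeing the data; the rest were fixed before. The number of changed genes (788, with 317 higher and 471 lower) was the least stable result. Leaving out a library moved it between 1 and 2284, higher genes between 0 and 1178 and lower genes between 1 and 1106. The 1 call without wild-type replicate 2 was IGLL1, where 2914 genes had an unadjusted p under 0.05. A lone knockout-labelled library is assumed to vary like the others, and leaving out a single copy of the identical columns changes nothing. Counts over 1.5 times the main ones came from no low-count filter (1272, 559 higher, 713 lower), DESeq2 (2776, 1198 higher, 1578 lower) and limma-voom with quality weights (4638, 2420 higher, 2218 lower). The added fits gave 3505 (1714 higher, 1791 lower) with the identical columns as 2 libraries and 2440 (1182 higher, 1258 lower) with both doubted libraries left out. The W-linked share as a covariate gave 158 (24 higher, 134 lower). Upper-quartile factors gave 500 and library totals 484 higher genes, and the median of all genes moved by at most 0.11 between scalings. An adjusted p under 0.01 left 2 genes, 0 higher and 2 lower, and a log2 change of at least 1 left 499 (186 higher, 313 lower), both by construction. The cause of the other shifts was not tested.

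Whether the shared replicate numbers pair the samples could not be decided. There are at most 2 pairs, and the deviations of the 2 knockout-labelled libraries from their mean mirror each other. The correlations of deviations from group means lay between -0.11 and 0.11. They were 0.11 for the libraries called replicate 1 and 0.09 for those called replicate 3, the highest values. With the replicate block, a wild-type library without a knockout-labelled partner adds nothing to the genotype effect. That is wild-type replicate 2 with the identical columns as replicate 1, and wild-type replicate 1 with them as replicate 2. Each fit thus also sets a library aside, so the gap between them does not bear on pairing alone. Taking the identical columns as replicate 1 gave 425 calls (125 higher, 300 lower) and as replicate 2 gave 2745 (1463 higher, 1282 lower). With the latter, the progenitor list did not pass (adjusted p = 0.0604) and the ribosomal and mitochondrial lists did (0.00627 and 4.68e-05); with the former, the erythroid list passed (0.00026), as it did without wild-type replicate 2. Of the 788 genes, every one tested kept its direction under each alternative, which their choice from the same libraries favours. Of 24 lists, 14 passed with camera's preset correlation, 12 to 15 without a library, 0 with an estimated correlation (smallest adjusted p 0.51) and 2 with fry (B cells and macrophages). The RAG1 difference stayed short of the threshold throughout, at log2 fold changes of 0.24 to 1.0.

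Reversals were small values around 0. Without a library EEF1A1 ranged from -0.28 to 0.023 (without wild-type replicate 3). LOC776816 reached 0.0090 with upper-quartile factors, 0.035 with library totals, 0.0010 with quality weights, and -0.13 to 0.046 without a library (0.046 without wild-type replicate 3). The plasma cell median reached 0.0010 with upper-quartile factors, 0.029 with library totals, 0.033 with quality weights, and -0.14 to 0.062 without a library (0.0050 and 0.062 without wild-type replicate 1 and knockout-labelled replicate 3). The p53 median reached 0.017 with the replicate block (identical columns as replicate 2) and -0.21 to 0.0090 without a library (0.0090 without wild-type replicate 1). The chemokine median ranged from -0.020 (without wild-type replicate 2) to 0.27 without a library, and the erythroid median -0.010 with quality weights and -0.10 with both doubted libraries left out. Without wild-type replicate 3 the ribosomal median was 0.072 and the mitochondrial one -0.063, against -0.23 and 0.96 at the other end of their ranges without a library. Over named genes and their alternatives, 1442 values kept their side of the threshold, 142 newly passed, 228 no longer passed and 5 reversed; the cause was not tested. Corrections for GC content were not run, as no genome sequence was used. Depth limits only the rarest transcripts, such as V segments, where sums of a few counts carry wide intervals.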

Other observations

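The tests in this part were chosen after the results were seen, except that of mesenchyme against epithelium, which was set before its result. Genes below that lie outside the naming rule were also chosen after their values were seen.

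Near IGLL1, the non-coding gene LOC121106852, which overlaps its span, held 244 counts in wild-type and 0 in knockout-labelled libraries, at least 64-fold lower at a floor of 3 counts over the group. Outside that span but within 50 kb, no gene passed. VPREB3 had 73.7 ± 15.5 and 12.6 ± 11.4 CPM (log2 fold change -2.55, SE 0.59, adjusted p = 0.0563). VPS29L had 30.3 ± 7.7 and 8.67 ± 5.47 CPM (adjusted p = 0.0613) and CHCHD10 had a log2 fold change of -1.06 (adjusted p = 0.0734). Adjusted p was 0.389 for SMARCB1 and 0.872 for DGCR2. Among genes elsewhere that passed the threshold, the proton channel gene HVCN1 fell from 556 ± 71.7 to 81.1 ± 25.5 CPM (-2.78, SE 0.26, adjusted p = 0.0246), CD38 by 1.77 (adjusted p = 0.0326) and MEF2C, on the Z chromosome, by 1.72 (adjusted p = 0.0361). IL7, a lymphocyte growth factor, rose from 7.8 ± 1.16 to 17.7 ± 0.796 CPM (1.18, SE 0.21, adjusted p = 0.0378), as did the vascular addressin gene MADCAM1 (0.85, SE 0.17, adjusted p = 0.0451). Each of these calls was lost in at least the fits without wild-type replicate 2 and without knockout-labelled replicate 3.

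The knockout-labelled libraries differed from each other. Replicate 1 lay above replicate 3 in 25 of 31 B cell genes (median log2 difference 0.42) and in all 32 cell cycle genes (0.49). It lay above replicate 3 in 5 of 34 mesenchyme genes (median -0.18). With 1 library each, no test of this difference was made. In wild-type, the mean log2 CPM of the B cell list was 7.18 in all 3 libraries, against 6.03 and 5.44 in knockout-labelled replicates 1 and 3.

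The immunoglobulin genes IGLL1 and VH26L1 fell further than other B lineage genes. IGLL1 lay -4.68 (log2, combined SE 0.67) below the next lowest member of the B cell list, TNFRSF13C, which restates the pattern and does not exclude that B lineage cells were fewer. A candidate explanation is that transcripts of rearranged immunoglobulin genes are missing, since V segments on chromosome 35 had a log2 fold change of -6.90 (SE 0.82), also beyond that of TNFRSF13C. It remains open whether the loss lies in rearrangement, in transcription of these loci or in the cells that carry them. V segments on chromosome 27 lay lower too. Those on chromosome 2 (239 and 197 counts) and chromosome 1 (9 and 18 counts) did not pass. Which antigen receptor the segments on chromosomes 27, 2 and 1 belong to was not determined, so nothing about immunoglobulin genes is drawn from them. Carry-over from other libraries stays open for the IGLL1 reads left in knockout-labelled replicate 1: 12 of 19 abundant W genes had no read there, against 1.32 expected if they had kept the same 0.65% as IGLL1, but that measure was chosen after the values were seen and their summed level, 0.86%, was no lower than that of IGLL1, with 102 of the 108 reads in 3 genes.

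B lineage genes lay lower while lists of other cell types lay higher. A lower share of B lineage cells that raised all other types alike would leave mesenchyme level relative to epithelium. Mesenchyme lay higher relative to epithelium by 0.44 in mean log2 CPM (pooled SD 0.19), which met the rule set beforehand for arguing against that explanation. Wild-type libraries lay at 0.35 to 0.81 and knockout-labelled ones at 1.02 and 1.03. The wild-type libraries alone spread about as widely as the shift, so the test does not decide. The margin between the groups is narrow. A lower share that raised all other types alike stays open, as does a lower share together with a change in stroma. A scaling moves all genes of a library alike. It is therefore argued against as the cause of the distance between the B cell and mesenchyme lists. Under the 4 scalings the B cell median was -1.337 to -1.225 and the mesenchyme median 0.83 to 0.94. Whether scaling sets where 0 lies stays open, because the 4 scalings shift the median of all genes by at most 0.11. They thus could not bring the mesenchyme median to 0. The B cell median was -1.52 with the W-linked share as a covariate, against -1.31 without it. That share differs most between knockout-labelled replicates 1 (0.00344%) and 3 (0.167%), which also differ in B cell level, so this fit alone does not decide on sex. In wild-type the list's mean log2 CPM was 7.18 in all 3 libraries, at W-linked shares of 0.0412% to 0.146%. Sex of the embryos is argued against for the B cell list only to that extent. The median of -1.63 without wild-type replicate 1 and knockout-labelled replicate 1 rests on 1 knockout-labelled library, the one with the lower B cell level.

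Wild-type replicate 1 held fewer W-linked reads than the other wild-type libraries, with a median of 26.9% of their level over 19 W genes (quartiles 19.5% and 33.1%). A single ZW embryo with low W-linked expression is argued against by Z-linked genes, which lay 0.46 (median log2) above wild-type replicates 2 and 3, themselves 0.04 apart. Admixture of a knockout-labelled library is argued against by IGLL1, which kept 93.6% of its level. A mixture of ZZ and ZW material, such as pooled embryos or mixed libraries, stays open: the Z-linked level lay 0.089 above the 0.37 computed from the W-linked share, and nearer to the 0.49 between knockout-labelled replicates 1 and 3. The labels give no sex.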
